A study of Mus musculus with 24 samples.

How the data were processed

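RNA-seq libraries from NIH-3T3 cells carrying RIPK3-2xFV were analysed in 12 groups of 2, as the sample labels assign them, in 2 experiments of 12 libraries. The submitters describe 2 biological replicates per condition, and p-values use a spread pooled over groups. Per the labels, cells were plated 16 h before treatment, RNA was isolated with a column kit and libraries were made with a stranded total RNA kit. All libraries came from 1 run and 1 pool, so no batch could be separated. How polysomes were isolated is not given in the sources used here. The file headers name the total RNA libraries of the snapshot input.

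The gene table deposited by the authors is titled RPKM, but per the file headers its values are read counts per gene. All of its values were whole numbers, and in all 24 libraries their sum equalled the exonic reads of the alignment summary, so they were treated as raw counts. Reads had been aligned with GSNAP, per the submitters' processing notes, which give neither its version nor the counting rule, so it is not known whether reads were counted by strand, and genes that overlap or have near-identical copies are uncertain. Other values in the deposited tables, per the file headers, are gene and chromosome lengths in bases and the median count of each group. Reads per alignment class, per chromosome and per genomic region class are deposited as read counts too. The authors also deposited log2 fold changes between groups, computed with limma per the submitters' processing notes. The adjusted p-values beside them were made by the authors, are rounded in the tables, and genes with low expression are listed there at a log2 of 0 with a p-value of 1. These placeholders, 74.8% to 77.1% of the genes in a table, were taken as no value. The sheet named for 0.5 h against untreated holds the 1 h comparison, and the sheet named for 4 h against untreated equals that of total RNA in the snapshot, as matched on their median counts.

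The submitters' notes name the genome build mm9, but the length of chromosome 1 in the files (195471971 bases) is that of GRCm38, and 99.9% of the 52403 gene identifiers found in GENCODE M21 overlapped their position there. Coordinates are therefore given as GRCm38, as in the files. The table holds 52636 genes, of which 25365 had no read in any library, and 99 symbols belong to several identifiers.

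Depth was the total gene count per library. Intronic reads made up 5.54% to 8.91% of reads in the time course, 2.05% to 2.65% in total RNA and 2.42% to 3.65% in polysome RNA. Genes with an RPKM of at least 0.5 in at least 2 libraries were kept, RPKM being computed here from the counts and the deposited lengths. This left 13507 genes in the time course, 13032 in the snapshot experiment and 13963 for the comparison of both. Counts were scaled by TMM and fitted with the edgeR quasi-likelihood test (edgeR 4.0.16, R 4.3.3), with 1 coefficient per group over the 12 libraries of an experiment, or all 24 for the comparison of experiments. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called higher or lower. The biological coefficient of variation was 0.122, 0.203 and 0.167. The standard error is the log2 fold change divided by the root of its F statistic. The design made before the data were examined assumed limma on log2 of RPKM plus 0.5, since the table was named RPKM; that fit was kept as an alternative, and edgeR was used because the values are counts.

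There were 16 comparisons. In the time course, dimerizer at 0.5, 1, 2, 3 and 4 h was compared with untreated cells, and 4 h with 0.5 h. In the snapshot, dimerizer and TNF were compared with untreated cells and with each other in total and in polysome RNA. Further comparisons were the change of the ratio of polysome to total RNA with each stimulus, polysome with total RNA in untreated cells, and the 4 h dimerizer response of total RNA in the snapshot minus that in the time course. For the 4 h time course comparison and the 4 comparisons with untreated cells in the snapshot, the genes named were the 8 largest rises and 8 largest falls in log2 RPKM plus 0.5. These were taken among called genes with a mean RPKM of at least 2 in the higher group and both libraries of a group above both of the other. For other comparisons they were the 4 largest of each. In each fixed list, up to 4 called members with the largest change were taken, or the 2 of highest expression when none was called, and 10 genes were always reported: Ripk3, Mlkl, Ripk1, Cxcl1, Il6, Ccl2, Cxcl10, Tnf, Nfkbia and Tnfaip3. Among the largest changes, predicted genes (Gm), clone names (Rik), symbols beginning with Mir, Snor, Rnu or Rn, and pseudogenes were counted but not named. Other genes named in the text were members of lists.

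The 19 gene lists were NF-kB targets and feedback, cytokines and chemokines, immediate early genes, MAP kinase phosphatases and feedback, interferon-stimulated genes, the unfolded protein and integrated stress response, heat shock response, p53 targets, cell death machinery, cytosolic ribosomal proteins, mitochondrially encoded mRNAs, cell cycle, replication-dependent histones, cholesterol biosynthesis, fibroblast matrix and contractile genes, matrix proteases and tissue inflammation, TGF-beta and BMP early targets, oxidative stress (Nrf2 targets) and markers of other cell types. The groups, comparisons, tests, lists, naming rule and alternatives named as planned were fixed before the data were examined. Lists with at least 5 measured members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Of 161 list calls, 91 held with the estimated correlation.

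Folds against a group without counts were computed against a floor of 3 counts over the group and are lower bounds. With 1 to 3 counts in a group, the ratio of counts is given with its 95% counting interval. For comparisons that share controls, 20 simulations of unchanged groups gave the correlation that the shared libraries produce. Shares of reads on the mitochondrial chromosome, in introns and between genes were correlated with time over the 12 time course libraries by permutation (100000 permutations, 2-sided, adjusted over 3 classes).

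The procedure was tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. For 0.5 h, 86 and 100 of them were recovered, and for 4 h in the time course 66 and 95. For dimerizer in total RNA 26 and 88 were recovered, in polysome RNA 19 and 88, and for the ratio with dimerizer 5 and 61. For polysome against total RNA the numbers were 25 and 88, and for the comparison of experiments 17 and 92. Between 1 and 11 of the 12832 to 13763 unchanged genes were called.

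Alternatives planned were median-of-ratios scaling, limma with pseudocounts of 0.1 and 1 (library totals as scaling), no expression filter, 1 model of all 24 libraries, each library left out in turn, a replicate block, an estimated list correlation and the authors' tables. Chosen after seeing the data were limma with the pseudocount of 0.5 as an alternative (it had been the planned main test), DESeq2 (1.42.0), removal of each library's trend with gene length (lowess span 0.3), and models of the 6 total or 6 polysome libraries alone. So were leaving out the libraries that stood apart from comparisons they are not part of, and the authors' tables for further comparisons. A group left with 1 library was assumed to vary like the others. Tables were handled with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.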

Results

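RNA was sequenced from NIH-3T3 mouse fibroblasts carrying RIPK3-2xFV, a form of the kinase RIPK3 that a small-molecule dimerizer joins into active complexes. Ripk3 counts may include RIPK3-2xFV. RIPK3 activation phosphorylates MLKL, which permeabilises the plasma membrane and ends in necroptosis, a lytic form of programmed cell death. The 24 libraries form 12 groups of 2. In the time course, cells were left untreated or received dimerizer (10 uM) for 0.5, 1, 2, 3 or 4 h. In the snapshot experiment, cells were left untreated or received dimerizer or TNF (20 ng/ml), an inflammatory cytokine, for 4 h, and both total RNA and polysome RNA, the mRNA bound to several ribosomes, were sequenced. Reads counted in genes numbered 8795755 to 32075134 per library in the time course, 18815525 to 32755567 in total RNA and 9635956 to 19363668 in polysome RNA. Expression values are TMM-scaled read counts per library size (CPM, mean ± SD, n = 2). Log2 fold changes are given ± SE with adjusted p-values from edgeR. Intervals and floors cover counting error only.

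The time course asks when, after RIPK3 is activated, the fibroblasts change their mRNA. At 0.5 h the chemokine Cxcl1 (chromosome 5, 90891241 to 90893115, GRCm38) stood at 130.4 ± 5.39 CPM against 5.94 ± 0.848 CPM in untreated cells, a 22.0-fold rise (log2 4.46 ± 0.16, adjusted p = 1.67e-07). Zfp36, which encodes an mRNA-destabilising protein, rose 10.4-fold (3.38 ± 0.09), and the cytokine gene Lif rose by 3.09 ± 0.10. The NF-kB inhibitors Nfkbia and Tnfaip3 rose by 3.00 ± 0.10 and 3.47 ± 0.17, and the chemokine Ccl2 by 2.33 ± 0.13. Ripk3 (−0.08 ± 0.22), Mlkl (−0.04 ± 0.09) and Ripk1 (−0.04 ± 0.12) did not pass the test, and Tnf had 5 counts against 0. Of 13507 genes tested, 46 were higher and 1 was lower.

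At 0.5 h, 5 lists were called both with the preset and with an estimated correlation. Of 25 immediate early genes measured, which encode fast-acting transcription factors, 12 rose and 18 did when adjusted over the list alone, with Fos at 2.76 ± 0.16, Btg2 at 1.78 and Nr4a1 at 1.72. Of 21 cytokines and chemokines 7 rose (12 adjusted over the list alone), and Cxcl2, without counts in untreated cells, was at least 15.3-fold higher. Of 23 NF-kB targets 6 rose (7 adjusted over the list alone), and of 15 MAP kinase feedback genes 4 rose (7 adjusted over the list alone), led by the phosphatase gene Dusp1 at 2.29 ± 0.09. Matrix proteases and inflammation genes had 2 of 17 risen (4 adjusted over the list alone) and an adjusted p = 0.0123 with an estimated correlation. The list of TGF-beta and BMP targets passed the list test with 0 of 14 members called (4 adjusted over the list alone), and not with an estimated correlation (adjusted p = 0.0594). Unfolded protein response genes (3 of 24 risen, 3 adjusted over the list alone), matrix genes and mitochondrial mRNAs also lost their list call. They had adjusted p = 0.158, 0.311 and 0.459 with an estimated correlation. Il6 (2.18 ± 0.29, adjusted p = 0.00811) lost its call without replicate 1 of the 0.5 h group (1.95, adjusted p = 0.0738). It also did without untreated replicate 1 or 2 (2.17 and 2.18, adjusted p = 0.174 and 0.139). Cxcl10 (3.72 ± 0.51) lost its call without any of the 4 libraries compared (3.73, 3.69, 3.64 and 3.78, adjusted p = 0.0604, 0.0770, 0.1995 and 0.146). With limma at a pseudocount of 1 both genes lost it too (1.076 and 0.687, adjusted p = 0.167 and 0.641), and Cxcl10 also at 0.5 (1.114, adjusted p = 0.167). The 47 calls became 22 and 24 without replicate 1 or 2 of the 0.5 h group, 19 and 23 without untreated replicate 1 or 2, and 84 without replicate 2 of the 1 h group.

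At 1 h Lif reached log2 6.46 ± 0.12 and Cxcl1 6.41 ± 0.18 (84.9-fold). Tnfaip3 stood at 5.51 ± 0.18, Il6 at 5.25 ± 0.28 and Ier3, a stress-induced survival gene, at 4.53 ± 0.12. Tnf, with 43 counts against 0, was at least 19.2-fold higher. The largest falls were small. Lipt1, a lipoyl transferase gene, dropped by 1.21 ± 0.17 and Ap5b1 by 1.13 ± 0.22. Txnip, which encodes a thioredoxin-binding protein, dropped by 1.09 ± 0.11, and Pdp1, a pyruvate dehydrogenase phosphatase gene, by 1.06 ± 0.10. In this order the falls missed the threshold in the authors' table (−1.235, −1.143, −1.097 and −1.074, adjusted p = 0.172, 0.106, 0.058 and 0.095), and Ap5b1 missed it without untreated replicate 1 (−1.18, adjusted p = 0.0873) or 2 (−1.15, adjusted p = 0.0916). Of 23 NF-kB targets 17 rose (21 adjusted over the list alone), as did 16 of 21 cytokines (18 adjusted over the list alone), 10 of 17 matrix protease and inflammation genes (14) and 8 of 15 MAP kinase feedback genes (10). Immediate early genes counted 18 rises and 1 fall among 25 (19 and 1 adjusted over the list alone), with the nuclear receptor gene Nr4a3 at 5.61. TGF-beta targets counted 7 rises among 14 (9 adjusted over the list alone). The p53 targets had 4 of 19 members risen (adjusted p = 0.0282 with an estimated correlation). Of 15 lists called at 1 h, 7 held with an estimated correlation. Unfolded protein response genes (7 of 24 risen), Nrf2 targets (3 of 16), markers of other cell types (1 of 5, median 0.47), cell death genes (1 of 21) and cell cycle genes (1 of 32 fallen) lost their list call. These lists had adjusted p = 0.0522, 0.0541, 0.0568, 0.0971 and 0.0971 with an estimated correlation. Matrix genes (3 of 25 risen), mitochondrial mRNAs (1 of 13) and ribosomal protein genes (0 called) lost it as well, with adjusted p = 0.191, 0.243 and 0.457.

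At 1 h, 361 genes were higher and 182 lower. Of these calls 66.5% were higher, or 51.3% with limma on log2 RPKM plus 0.5, where each library is scaled by its total. The 1 h libraries differed from each other with an SD over genes of 0.353 in log2, against 0.0699 to 0.175 in the other pairs of the time course. The call count of 543 became 3992 without replicate 1 of this group, 1059 without its replicate 2, and 242 and 256 without untreated replicate 1 or 2.

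At 2 h, 1690 genes were higher and 1647 lower, or 854 and 3536 with limma and library totals. Ripk3 (0.54 ± 0.22) did not pass, but was called without the expression filter (0.49, adjusted p = 0.00576), without replicate 2 of the 1 h group (0.50, adjusted p = 0.00539) and in the authors' table (0.539). Il6 reached 7.93 ± 0.30 (243.8-fold), Csf3, the granulocyte colony-stimulating factor gene, 7.87 ± 0.54, Lif 7.67 ± 0.12 and Cxcl1 7.47 ± 0.18. Tnf was at least 38.5-fold higher, its largest bound of the course. Mrnip, a DNA repair gene, fell by 2.63 ± 0.25, Fam46b by 2.15 ± 0.15, Mn1 by 1.88 ± 0.17 and Cyr61, a matricellular target of the YAP and SRF pathways, by 1.73 ± 0.09. Ripk1, the kinase upstream of RIPK3, rose by 0.68 ± 0.12 (adjusted p = 0.00267). Of 23 NF-kB targets 21 rose, of 21 cytokines 18 and of 17 matrix proteases and inflammation genes all 17. Of 32 cell cycle genes 13 fell (adjusted p = 0.0274 with an estimated correlation). Nrf2 targets, the oxidative stress list, had 7 of 16 members risen (adjusted p = 0.0355 with an estimated correlation), and cell death genes 9 risen and 2 fallen (adjusted p = 0.0451 with an estimated correlation). Of 14 lists called at 2 h, 9 held with an estimated correlation. The mitochondrial mRNAs (9 of 13 risen), heat shock genes (6 of 17), TGF-beta targets (7 risen and 3 fallen), matrix genes (9 and 1 of 25) and markers of other cell types (1 of 5 risen, median 0.68) lost their list call. In this order they had adjusted p = 0.168, 0.162, 0.162, 0.231 and 0.127 with an estimated correlation. The 3337 calls became 1581 and 1782 without replicate 1 or 2 of the 2 h group, 1813 and 1819 without untreated replicate 1 or 2, and 5620 without replicate 2 of the 1 h group.

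At 3 h Csf3 stood at 9.50 ± 0.54, Cxcl1 at 8.03 ± 0.19, Lif at 7.81 ± 0.12, and Cxcl2 was at least 2004-fold higher. Ctgf, the connective tissue growth factor gene (chromosome 10, 24595442 to 24598683), fell by 3.50 ± 0.12 and Mrnip by 3.54 ± 0.30. Id2, a BMP-responsive repressor gene, fell by 2.45 ± 0.14 and Fignl1 by 2.29 ± 0.11. Of 32 cell cycle genes 20 fell and 2 rose, with the mitotic kinesin gene Kif20a at −1.44 ± 0.09 (adjusted p = 0.0147 for the list with an estimated correlation). Of 15 interferon-stimulated genes 9 fell and 2 rose, with Ifit1 at −2.16 ± 0.36, and the list call was lost with an estimated correlation (adjusted p = 0.111). Nrf2 targets had 9 of 16 risen, with the heme oxygenase gene Hmox1 at 4.05 ± 0.11 (adjusted p = 0.0147 for the list with an estimated correlation). Of 15 lists called at 3 h, 8 held with an estimated correlation. Besides the interferon list, cell death genes (10 rises and 4 falls), markers of other cell types (3 of 5 risen), mitochondrial mRNAs (8 of 13 risen), unfolded protein response genes (10 and 2), heat shock genes (9 and 1) and ribosomal protein genes (11 and 1) lost their call. In this order they had adjusted p = 0.0763, 0.105, 0.161, 0.161, 0.161 and 0.619. Ripk3 (0.83 ± 0.22, adjusted p = 0.0124) lost its call without replicate 1 of the 3 h group (0.66, adjusted p = 0.0914) and without untreated replicate 2 (0.64, adjusted p = 0.121), as well as with limma (0.45, adjusted p = 0.0988). At this time 2818 genes were higher and 2839 lower.

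At 4 h, 2801 genes were higher and 3034 lower than in untreated cells, and 2091 of them had changed at least 2-fold. Cxcl1 averaged 1847 ± 203.5 CPM against 5.94 ± 0.848 CPM (311-fold, log2 8.28 ± 0.19, adjusted p = 1.31e-09). Csf3 rose 1321-fold (10.37 ± 0.54, from 10 counts in untreated cells), Il6 280.4-fold (8.13 ± 0.30) and Cxcl2 at least 3787-fold. Lif rose by 7.65 ± 0.12 and the EGF-family ligand gene Ereg by 6.34 ± 0.23. Ccl2 reached 2483 ± 117.7 CPM (5.67 ± 0.15), and Il23a, an interleukin subunit gene, rose by 9.21 ± 0.45. Ctgf stood at 46.5 ± 6.59 CPM against 763 ± 64.8 CPM (−4.04 ± 0.12). The Notch-modifying enzyme gene Lfng fell by 3.85 ± 0.46, Mrnip by 3.06 ± 0.33, and Tmem119 by 2.83 ± 0.21. The sphingosine phosphate receptor gene S1pr3 fell by 2.46 ± 0.12, Chst12 by 2.39 ± 0.17, Filip1l by 2.27 ± 0.13 and Cyr61 by 2.24 ± 0.09.

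**Figure D1:**
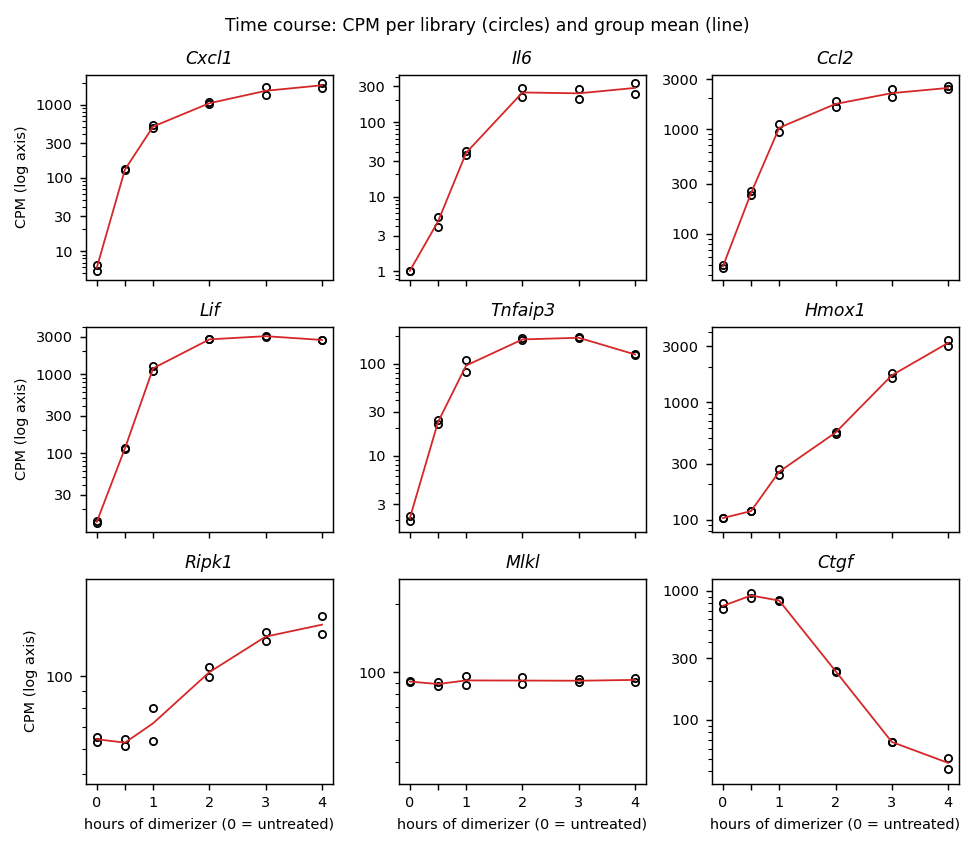
CPM (log axis) of 9 genes against hours of dimerizer, with untreated cells at 0 h. Circles are single libraries (2 per time) and the red line joins group means, with Cxcl1, Il6, Ccl2 and Lif climbing within 1 h, Hmox1 later, Mlkl level on this scale and Ctgf dropping after 1 h.

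Inflammatory lists moved together at 4 h. NF-kB targets counted 21 rises and 1 fall among 23 (the same counts adjusted over the list alone, adjusted p = 0.000877 with an estimated correlation). Among them stood Ier3 at 5.98 ± 0.13, Tnfaip3 at 5.91 ± 0.18, the signalling adaptor gene Traf1 at 4.92 and Nfkbia at 4.11 ± 0.11. The adhesion molecule gene Icam1 had a count ratio of 38.8 (95% counting interval 12.2 to 197). Cytokines and chemokines counted 19 rises and 1 fall among 21 (the same adjusted over the list alone), with a median of 4.72, or 4.52 with Cxcl2 and Tnf at their bounds. Tnf was at least 17.7-fold higher. Matrix proteases and inflammation genes counted 16 rises and 1 fall among 17 (the same adjusted over the list alone). The collagenase gene Mmp13 stood at 8.53 ± 0.28, the prostaglandin synthase gene Ptges at 5.54 and Lcn2 at 5.32, and the acute phase gene Saa3 had a count ratio of 1202 (95% counting interval 332 to 9947).

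Stress and growth lists also changed by 4 h. Nrf2 targets had 13 of 16 members risen (13 adjusted over the list alone, adjusted p = 0.00651 with an estimated correlation), including Hmox1 at 4.97 ± 0.12 and the autophagy receptor gene Sqstm1 at 2.20. Of 32 cell cycle genes 22 fell and 2 rose (23 and 2 adjusted over the list alone, adjusted p = 0.00942 with an estimated correlation), among them Kif20a at −1.48 ± 0.09, Ccne2 at −1.22 and Ccnb1 at −1.09. MAP kinase feedback genes counted 11 rises and 2 falls among 15 (the same adjusted over the list alone, adjusted p = 0.00942 with an estimated correlation), with Dusp4 at 4.32 ± 0.31 and Spry4 at 2.05. The p53 targets had 8 risen and 5 fallen of 19 (the same adjusted over the list alone, adjusted p = 0.0290 with an estimated correlation). They included the cell cycle inhibitor gene Cdkn1a at 2.19, Plk3 at 2.89 and Gadd45a at 2.64.

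Further lists were called at 4 h with the preset correlation only. Unfolded protein response genes counted 15 rises among 24 (16 adjusted over the list alone, adjusted p = 0.0666 with an estimated correlation), with the cystine transporter gene Slc7a11 at 4.18 and Ppp1r15a at 2.31. Cell death genes counted 10 rises and 2 falls among 21 (the same adjusted over the list alone, adjusted p = 0.0666 with an estimated correlation), with Bcl2l11 at 1.56 and the caspase inhibitor gene Cflar at 1.31. Immediate early genes counted 18 rises and 4 falls among 25 (the same adjusted over the list alone, adjusted p = 0.0744 with an estimated correlation), with Nr4a3 at 3.90 and Nr4a2 at 3.09. Interferon-stimulated genes counted 8 falls and 2 rises among 15 (the same adjusted over the list alone, adjusted p = 0.0744 with an estimated correlation), with Ifit1 at −3.73 ± 0.58, Rtp4 at −3.19, Xaf1 at −2.86 and Ifit2 at −2.05. Heat shock genes had 11 of 17 risen (11 adjusted over the list alone, adjusted p = 0.136 with an estimated correlation), with Hspa8 at 1.32 (from 2.78 CPM). Ribosomal protein genes had 22 risen and 1 fallen of 47 (23 and 1 adjusted over the list alone, adjusted p = 0.575 with an estimated correlation), with Rpl38 at 1.78 (from 0.4 CPM).

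Mitochondrial mRNAs had 11 of 13 risen at 4 h (11 adjusted over the list alone, adjusted p = 0.0744 with an estimated correlation), with mt-Co2 at 2.70 (from 5.24 CPM). In parallel the share of reads on the mitochondrial chromosome went from 2.65% ± 0.13 in untreated cells to 5.04% ± 0.84 at 4 h (SD, n = 2). Over the 12 libraries it was correlated with time (Pearson r = 0.928, Spearman rho = 0.975, permutation adjusted p = 3e-05 for both). This is the smallest p the permutations allow over 3 read classes, and r was 0.947 without the 4 h libraries. Unmapped reads also rose, to 8.96 ± 4.03 per 100 uniquely mapped reads at 4 h against 1.66 ± 0.36 in untreated cells. The 4 h libraries were the shallowest of the course (8795755 and 11899355 counts). In total RNA of the snapshot the mitochondrial share was 3.26% with dimerizer and 2.67% untreated.

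Markers of other cell types, genes of leukocytes, epithelium and endothelium, had 2 rises and 1 fall among 5 measured (the same adjusted over the list alone, adjusted p = 0.1004 with an estimated correlation). The members that moved were Cd14, an endotoxin co-receptor that fibroblasts can also induce, at 2.88, the cadherin gene Cdh5 at 1.94 and the macrophage receptor gene Csf1r at −1.08. No list call was made for 3 lists. Cholesterol biosynthesis had 9 rises and 2 falls of 20 (11 and 2 adjusted over the list alone), with Insig1 at 1.07 and Mvk at −1.29. TGF-beta targets had 7 and 4 of 14 (7 and 5 adjusted over the list alone), with Sox9 at 2.64 and Id2 at −2.25. Fibroblast matrix genes had 9 and 11 of 25 (10 and 13 adjusted over the list alone). In the matrix list Postn stood at 2.61, Dcn at 1.79 and Col3a1 at −1.85, and its median (−0.47), mean (0.026) and test (downward, camera adjusted p = 0.893) differed in sign. Replication-dependent histones had too few measured members in the time course to be tested.

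Of pathway genes, Ripk1 rose by 1.17 ± 0.13 at 4 h (adjusted p = 5.00e-05). Ripk3 stood at 0.71 ± 0.22 (adjusted p = 0.0252), a call that ended without replicate 1 or 2 of the 4 h group (0.77 and 0.65, adjusted p = 0.0688 and 0.117). It also ended without untreated replicate 1 or 2 (0.84 and 0.54, adjusted p = 0.0536 and 0.176) and with limma (0.32, adjusted p = 0.215). Mlkl did not pass (0.02 ± 0.10), but with library totals and limma it was called lower at 4 h (−0.36, adjusted p = 0.0104). With library totals as scaling the median of all genes moved to −0.10 at 1 h, −0.24 at 2 h, −0.35 at 3 h and −0.41 at 4 h. Changes are given relative to that median. With limma on that scale 18.6% of the calls at 4 h were higher instead of 48.0%, 18.7% instead of 49.8% at 3 h and 19.5% instead of 50.6% at 2 h. The medians of p53 targets (0.25) and cell death genes (0.25) at 4 h then lie below 0, at −0.13 and −0.13.

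The comparison of 4 h with 0.5 h separates late from early changes. Csf3 gained a further 8.73 ± 0.47, Cxcl2 7.96 ± 0.26, Il23a 7.53 ± 0.38 and Il6 5.95 ± 0.26, while Cxcl1 gained 3.82 and Nfkbia 1.11. Ctgf fell by 4.31 ± 0.13, Tmem119 by 3.00 ± 0.21, Cyr61 by 2.87 ± 0.09 and S1pr3 by 2.54 ± 0.13. Cytokines counted 19 rises and 1 fall, NF-kB targets 20 and 1, matrix proteases and inflammation genes 15 and 1, and Nrf2 targets 12 rises among 16 (adjusted p = 0.00528 with an estimated correlation). Cell cycle genes counted 24 falls and 2 rises among 32 (25 and 2 adjusted over the list alone, adjusted p = 0.0104 with an estimated correlation). Immediate early genes went both ways, with 9 rises and 10 falls among 25 (10 and 11 adjusted over the list alone), no list call (camera adjusted p = 0.378) and a median (0.023) and mean (−0.014) of opposite sign. Of 13 lists called between 0.5 and 4 h, 5 held with an estimated correlation. Those lost were p53 targets, MAP kinase feedback genes, cell death genes, interferon-stimulated genes, mitochondrial mRNAs, unfolded protein response genes, heat shock genes and ribosomal protein genes. In this order they had adjusted p = 0.0532, 0.0573, 0.0722, 0.0989, 0.0989, 0.0994, 0.147 and 0.664. For TGF-beta targets the median (0.050) and mean (−0.078) differed in sign. Over the whole course, 1306 genes rose at least 2-fold at some time. Their highest mean was at 0.5 h for 3 of them, at 1 h for 48, at 2 h for 112, at 3 h for 411 and at 4 h for 732. Of 19 such immediate early genes 8 were highest at 1 h, and of 19 cytokines 13 were highest at 4 h.

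Between 0.5 and 4 h, 2686 genes were higher and 2949 lower, with 47.7% of the calls higher, or 18.9% with limma and library totals. Library totals alone moved the median of all genes to −0.38. Ripk3 (0.79 ± 0.22) lost its call without replicate 1 or 2 of the 4 h group (0.85 and 0.74, adjusted p = 0.0507 and 0.0839) or of the 0.5 h group (0.71 and 0.84, adjusted p = 0.104 and 0.0642). Cxcl10 (1.01 ± 0.34) lost it without replicate 1 of the 4 h group (0.70, adjusted p = 0.244) or either 0.5 h library (0.97 and 1.01, adjusted p = 0.111 and 0.107). It also lost it with limma at pseudocounts of 0.1, 0.5 and 1 (0.59, 0.43 and 0.31, adjusted p = 0.0983, 0.130 and 0.169) and with 1 model of all 24 libraries (1.01, adjusted p = 0.0617). Ripk3 lost it with limma too (0.43 at a pseudocount of 0.5, adjusted p = 0.109). Tnf (3.46 ± 0.69) lost it without replicate 2 of the 4 h group (2.73, adjusted p = 0.0791).

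In the snapshot experiment, total RNA after 4 h of dimerizer repeats the late time point in separate cultures. Cxcl1 averaged 6151 ± 419.9 CPM against 7.71 ± 0.887 CPM (797-fold, log2 9.64 ± 0.43). Csf3 rose 5600-fold (12.45 ± 0.45) and Il6 918-fold (9.84 ± 0.22). Lif rose by 8.42 ± 0.24, Ereg by 7.13 ± 0.19, Ccl2 by 6.51 ± 0.25 and Ier3 by 6.45 ± 0.27. Cxcl2 had a count ratio of 24590 (95% counting interval 4413 to 971400). Lfng fell by 3.63 ± 0.50, Ctgf by 3.44 ± 0.28, Mfsd9 by 3.28 ± 0.26, Id2 by 2.65 ± 0.25, and the endosialin gene Cd248 by 2.40 ± 0.23. The homeobox genes Hoxa2 and Hoxa3, which set positional identity, fell by 3.10 ± 0.37 and 2.80 ± 0.31. Ripk3 (−0.12 ± 0.19) and Mlkl (0.10) did not pass. Ripk1 (1.06 ± 0.28, adjusted p = 0.0267) lost its call without replicate 1 or 2 of the dimerizer group (1.03 and 1.08, adjusted p = 0.128 and 0.0971). It also lost it without replicate 1 or 2 of the untreated group (1.04 and 1.07, adjusted p = 0.149 and 0.138) and with limma (0.70, adjusted p = 0.0785).

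In total RNA, NF-kB targets counted 20 rises and 2 falls among 24 (21 and 2 adjusted over the list alone). Cytokines counted 20 rises among 23 (20 adjusted over the list alone), with Il23a at least 848-fold higher. Matrix proteases and inflammation genes counted 14 rises among 18 (16 adjusted over the list alone), with Mmp13 at 7.21. MAP kinase feedback genes counted 11 rises and 1 fall among 14 (11 and 2 adjusted over the list alone, adjusted p = 0.00529 with an estimated correlation). Immediate early genes counted 21 rises and 1 fall among 25 (22 and 1 adjusted over the list alone, adjusted p = 0.0220 with an estimated correlation), with Nr4a1 at 3.85 and Fosb at 3.50. Cholesterol biosynthesis genes, targets of the sterol-sensing factor SREBP, had 15 of 20 risen (17 adjusted over the list alone, adjusted p = 0.0455 with an estimated correlation), including Insig1 at 2.03 and Msmo1 at 1.74. Unfolded protein response genes had 11 of 24 risen (13 adjusted over the list alone, adjusted p = 0.0220 with an estimated correlation), with Slc7a11 at 3.22 and the glutathione-degrading enzyme gene Chac1 at 2.59. Nrf2 targets had 6 of 16 risen (7 adjusted over the list alone, adjusted p = 0.0455 with an estimated correlation), with Hmox1 at 3.71 ± 0.17. The p53 targets (9 risen and 2 fallen of 19) and cell death genes (7 and 1 of 22) had adjusted p = 0.0455 each with an estimated correlation. The median of the cell death list (0.12) lies at −0.20 with library totals.

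Cell cycle genes had 7 of 32 fallen and mitochondrial mRNAs 2 of 13 risen, and their list calls were lost with an estimated correlation (adjusted p = 0.570 and 0.527). Interferon-stimulated genes (2 rises and 3 falls of 16, median −0.0015, mean 0.036), matrix genes (3 and 2 of 24, median −0.15, mean 0.033) and replication-dependent histones (1 fall of 15, Hist4h4 at −2.48, median 0.031, mean −0.41) were not called. Nor were heat shock genes (1 rise of 17), ribosomal protein genes (0 of 47), TGF-beta targets (4 and 3 of 14) or markers of other cell types (Cd14 at 2.86 and the epithelial cadherin gene Cdh1 at −1.79 of 6). In all, 1277 genes were higher and 1495 lower. Of these calls 46.1% were higher, or 19.2% with limma and library totals. Library totals alone moved the median of all genes to −0.36. The 2772 calls became 1166 and 1377 without replicate 1 or 2 of the dimerizer group, 1118 and 1119 without untreated replicate 1 or 2. They became 4227 and 4223 without replicate 1 or 2 of the polysome dimerizer group, 7610 with the total RNA libraries fitted alone and 7218 in the authors' table. The SD over genes within pairs was 0.557 for polysome dimerizer, 0.30 and 0.351 for other polysome and 0.0844 to 0.144 for total RNA.

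Across 12646 genes, log2 fold changes at 4 h of dimerizer in the time course and in total RNA of the snapshot had r = 0.765 and rho = 0.759, with genes not being independent replicates. Both experiments called 1072 genes higher, where 269.7 would be shared by independent lists, and 1197 lower, where 340.0 would. Of 2276 genes called in both, 7 had opposite directions.

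TNF was the other stimulus of the snapshot. In total RNA after 4 h of TNF the chemokine gene Ccl5 (chromosome 11, 83525778 to 83530518) rose 385-fold (8.59 ± 0.51) and Ccl2 78.0-fold (6.29 ± 0.25). Il6 rose by 6.62 ± 0.20, Lif by 6.30 ± 0.22, and Cxcl1, at 589 ± 9.92 CPM, by 6.25 ± 0.38. Saa3 rose by 6.85 ± 0.50 and the adhesion molecule gene Vcam1 by 5.18 ± 0.52. Count ratios were 4265 for Cxcl2 (95% counting interval 765 to 168500) and 386 for Cxcl10 (68.9 to 15300). The water channel gene Aqp5 fell by 4.71 ± 0.55 and Ctgf by 3.48 ± 0.28. Daam2 fell by 2.72 ± 0.31, Id2 by 2.13 ± 0.24, Gadd45g by 2.01 ± 0.27 and Spon2 by 1.98 ± 0.23. Ripk1 (0.44), Ripk3 (0.21) and Mlkl (0.16) did not pass. With the 6 total RNA libraries fitted alone all 3 were called higher (0.47, 0.24 and 0.19, adjusted p = 0.000447, 0.0171 and 0.0416), as they were in the authors' table (0.471, 0.238 and 0.189). NF-kB targets counted 21 rises among 24 (22 adjusted over the list alone), with Tnfaip3 at 5.28 and Nfkbia at 3.91, and cytokines 20 among 23 (21). Interferon-stimulated genes counted 8 rises among 16 (10 and 2 falls adjusted over the list alone, adjusted p = 0.00243 with an estimated correlation), with the GTPase genes Gbp2 and Gbp3 at 4.63 and 4.40 and Oasl2 at 2.47. Cell death genes had 8 of 22 risen (9 adjusted over the list alone, adjusted p = 0.00388 with an estimated correlation), including Bid at 1.48. The nucleic acid sensor gene Zbp1, which can engage RIPK3, had a count ratio of 20.1 (95% counting interval 6.52 to 100.4). Matrix proteases and inflammation genes had 9 of 18 risen (12 and 1 fall adjusted over the list alone).

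Immediate early genes (8 rises and 1 fall of 25, 18 and 1 adjusted over the list alone), MAP kinase feedback genes (5 and 2 of 14) and p53 targets (4 and 1 of 19, with the death receptor gene Fas at 5.53) lost their list call with TNF. They had adjusted p = 0.126, 0.0853 and 0.126 with an estimated correlation. No member of the cholesterol, Nrf2, heat shock, cell cycle, histone or ribosomal protein lists was called by edgeR over all genes. When adjusted over the list alone, 1 Nrf2 target passed. The spread is pooled with that of polysome RNA, which was wider, so this does not show these lists unchanged. In all, 380 genes were higher and 236 lower. Of these calls 61.7% were higher, or 50.4% with library totals and limma at a pseudocount of 1, and library totals moved the median of all genes to −0.11. The 616 calls became 3910 with the total RNA libraries fitted alone, and the authors' table has 5346.

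The responses to dimerizer and TNF in total RNA had r = 0.718 and rho = 0.637 across genes, but they share the untreated libraries, and unchanged groups simulated against these gave r = 0.458 and rho = 0.448. The covariance of 0.394 exceeded the simulated 0.0720 by 0.322 (20 simulations). Shared calls numbered 315 higher, against 37.2 for independent lists, and 194 lower, against 27.1, with 2 of 511 opposite. The simulated unchanged groups had 0 genes called in both. Whether the shared controls add shared calls among genes that did change was not tested. With the separate untreated cells of the time course, the 4 h dimerizer response and the TNF response had r = 0.556 and rho = 0.471. They shared 283 higher genes (74.8 for independent lists) and 183 lower genes (52.9), with 15 of 481 opposite.

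Tested directly in total RNA, dimerizer and TNF parted along several lists. Csf3 was 103-fold higher with dimerizer (6.69 ± 0.33). Nfkbiz, an NF-kB cofactor gene, was higher by 3.46 ± 0.28, Cxcl1 by 3.39 ± 0.33, Il11 by 3.30 ± 0.18 and Il6 by 3.23 ± 0.16. Ccl5 was lower by log2 −3.51 ± 0.36, Zfp41 by −2.54 ± 0.28, the gelatinase gene Mmp9 by −2.25 ± 0.31 and Nfkbie by −2.19 ± 0.21. Ccl2 (0.22 ± 0.20), Nfkbia (−0.07 ± 0.17), Tnfaip3 (−0.21 ± 0.25), Cxcl10 (−0.98 ± 0.34, adjusted p = 0.114), Ripk1 (0.61 ± 0.28) and Ripk3 (−0.33 ± 0.19) did not pass. Cxcl10 was called lower without the expression filter, with 1 model of all 24 libraries, with DESeq2 and with limma at a pseudocount of 0.5 or 1 (−0.96, −0.99, −0.96, −1.03 and −0.88, adjusted p = 0.0261, 0.0237, 0.0409, 0.0201 and 0.0165). With the total RNA libraries fitted alone Cxcl10 (−1.01, adjusted p = 0.00182), Ccl2 (0.21, adjusted p = 0.0467), Ripk1 (0.61, adjusted p = 7.20e-05) and Ripk3 (−0.34, adjusted p = 0.00193) passed. Ripk1 also passed with the gene length trend removed (0.55, adjusted p = 0.0270). Higher with dimerizer were 14 of 25 immediate early genes (18 adjusted over the list alone) and 8 of 14 MAP kinase feedback genes (11 adjusted over the list alone), with adjusted p = 0.0250 and 0.00689 with an estimated correlation. So were 7 of 24 unfolded protein response genes (7 adjusted over the list alone, adjusted p = 0.0192 with an estimated correlation), with Chac1 at 2.63 and Ppp1r15a at 2.17. Of 20 cholesterol genes 12 were higher (17 adjusted over the list alone, adjusted p = 0.0210 with an estimated correlation), with Insig1 at 2.06. Nrf2 targets had 2 of 16 higher (4 adjusted over the list alone, adjusted p = 0.0250 with an estimated correlation), with Hmox1 at 3.11. Lower were 6 of 16 interferon-stimulated genes (11 adjusted over the list alone, adjusted p = 0.00689 with an estimated correlation), with Gbp3 at −3.30 and Xaf1 at −2.23.

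**Figure D2:**
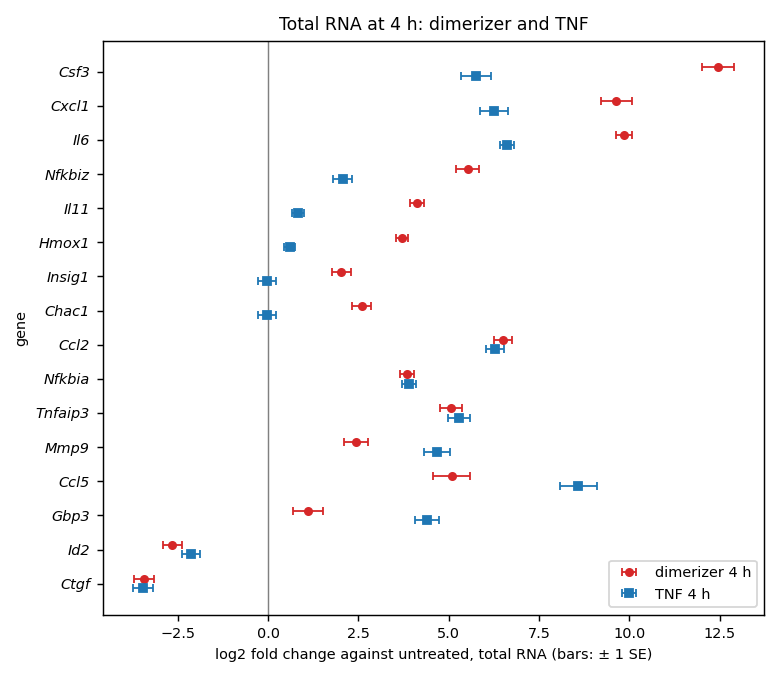
Log2 fold change against untreated cells in total RNA at 4 h for 16 genes, with dimerizer as red circles and TNF as blue squares (bars, 1 SE; n = 2 libraries per group). Csf3, Cxcl1 and Il6 lie higher with dimerizer, Ccl5, Mmp9 and Gbp3 higher with TNF, and the points of Ccl2, Nfkbia and Tnfaip3 nearly coincide.

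Cytokines went both ways between the stimuli, 11 higher and 4 lower with dimerizer among 23 (11 and 6 adjusted over the list alone, adjusted p = 0.0210 with an estimated correlation). NF-kB targets did likewise, 4 higher and 6 lower among 24 (6 and 8 adjusted over the list alone). They had no list call (camera adjusted p = 0.667) and a median (−0.22) and mean (0.008) of opposite sign. Matrix proteases (6 and 1 of 18), p53 targets (5 and 1 of 19), heat shock genes (1 higher of 17), mitochondrial mRNAs (0 called) and cell cycle genes (2 lower of 32) lost their list call. These lists had adjusted p = 0.0786, 0.161, 0.419, 0.556 and 0.598 with an estimated correlation. Of the cell death genes, Zbp1 stood at −2.37, Birc2 at −1.36 and Mcl1 at 1.13, without a list call. In all, 506 genes were higher and 545 lower with dimerizer. Of these calls 48.1% were higher, or 18.1% with limma and library totals. Library totals alone moved the median of all genes to −0.26 and the medians of the cytokine (0.25), Nrf2 (0.21) and p53 lists (0.14) to −0.0017, −0.042 and −0.11. The 1051 calls became 222 and 238 without replicate 1 or 2 of the dimerizer group, 162 and 133 without replicate 1 or 2 of the TNF group, 2256 without replicate 1 or 2 of the polysome dimerizer group, and 6043 with the total RNA libraries fitted alone.

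Polysome RNA asks whether the induced mRNAs were loaded on ribosomes. With dimerizer, Cxcl1 in polysomes averaged 6442 ± 2058 CPM against 4.56 ± 0.748 CPM (1413-fold, 10.46 ± 0.45). Il6 rose by 9.87 ± 0.22, Lif by 8.76 ± 0.24, Ier3 by 7.33 ± 0.28, Ereg by 7.18 ± 0.19 and Ccl2 by 6.97 ± 0.25. Count ratios were 16490 for Csf3 (95% counting interval 4566 to 136200) and 13410 for Cxcl2 (2407 to 529900). Hoxa2 fell by 3.53 ± 0.43 (in the authors' table −3.7, adjusted p = 0.052), Mfsd9 by 3.44 ± 0.27 and Mrnip by 3.35 ± 0.40. Ctgf fell by 3.16 ± 0.27, Hoxa3 by 3.15 ± 0.33, Rab7b by 2.64 ± 0.16 and Mn1 by 2.60 ± 0.23. The nuclear RNA Malat1 (−3.00 ± 0.68, adjusted p = 0.0130) lost its call without untreated polysome replicate 1 (−2.62, adjusted p = 0.0638), with the 6 polysome libraries fitted alone (−3.01, adjusted p = 0.0527) and in the authors' table (−3.18, adjusted p = 0.084). Ripk1 (0.89 ± 0.29, adjusted p = 0.0560), Ripk3 (−0.29 ± 0.19) and Mlkl (0.19 ± 0.24) did not pass. Ripk1 was called higher without the expression filter, with median-of-ratios scaling, with 1 model of all 24 libraries and with DESeq2 (0.90, 0.93, 0.91 and 0.93, adjusted p = 0.00610, 0.0410, 0.00647 and 0.00955). It also was with the gene length trend removed (1.13, adjusted p = 0.000280) and without replicate 1 of the dimerizer group (1.25, adjusted p = 0.00527), where Mlkl passed too (0.54, adjusted p = 0.0487). Ripk3 was called lower with limma (−0.63, adjusted p = 0.0295).

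In polysome RNA with dimerizer, 20 of 23 cytokines rose (20 adjusted over the list alone), with a median of 6.24, or 5.31 with members at their bounds. NF-kB targets counted 21 rises and 1 fall among 24 (21 and 2 adjusted over the list alone). Matrix proteases and inflammation genes had 14 of 18 risen (15 adjusted over the list alone, adjusted p = 0.00944 with an estimated correlation). Immediate early genes counted 21 rises and 1 fall among 25 (22 and 1 adjusted over the list alone), and MAP kinase feedback genes 10 rises among 14 (10 and 1). Unfolded protein response genes counted 14 rises among 24 (14 adjusted over the list alone), cholesterol genes 15 among 20 (17) and Nrf2 targets 6 among 16 (6), with Hmox1 at 3.83. These 5 lists had adjusted p = 0.0149, 0.00312, 0.0112, 0.0307 and 0.0149 with an estimated correlation. The p53 targets had 9 risen and 3 fallen of 19 (adjusted p = 0.0371 with an estimated correlation). Cell death genes had 8 of 22 risen (9 and 1 fall adjusted over the list alone, adjusted p = 0.0307 with an estimated correlation), with a median of 0.18 that lies at −0.15 with library totals. Mitochondrial mRNAs (4 of 13 risen), cell cycle genes (5 of 32 fallen) and ribosomal protein genes (2 of 47 risen, median 0.32, or −0.010 with library totals) lost their list call. In this order they had adjusted p = 0.385, 0.616 and 0.829 with an estimated correlation. Interferon-stimulated genes (3 and 3 of 16, median 0.13, mean −0.017) and matrix genes (4 and 1, median −0.21, mean 0.045) were not called. In all, 1258 genes were higher and 1295 lower. Of these calls 49.3% were higher, or 18.6% with limma and library totals. Library totals alone moved the median of all genes to −0.40. The 2553 calls became 4757 without replicate 2 of the dimerizer group, 1422 and 1553 without untreated polysome replicate 1 or 2, and 426 with the polysome libraries fitted alone.

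With TNF, polysome RNA gained Saa3 (7.24 ± 0.51), Ccl2 (6.47 ± 0.25), Il6 (6.13), Lif (6.01 ± 0.22), Cxcl1 (5.89 ± 0.38), Ccl7 (5.88 ± 0.47) and Vcam1 (5.25 ± 0.52). Count ratios were 2160 for Ccl5 (95% counting interval 387 to 85380) and 1238 for Cxcl2 (222 to 48970). Aqp5 fell by 5.06 ± 0.64 and Ctgf by 3.40 ± 0.28. Lower too were Daam2, which fell by 2.79 ± 0.34, the apelin gene Apln by 2.30 ± 0.26, Mfsd9 by 2.22 ± 0.25, Id2 by 2.16 ± 0.25 and Cd248 by 1.91 ± 0.23. The last 5 of these lost their call with the 6 polysome libraries fitted alone, at −2.78, −2.31, −2.22, −2.16 and −1.92. Hoxa2 (−2.32 ± 0.38) lost it there and without replicate 2 of the TNF group (−1.96, adjusted p = 0.0868). NF-kB targets counted 20 rises among 24 (22 and 1 fall adjusted over the list alone) and cytokines 19 among 23 (21). Interferon-stimulated genes counted 8 rises and 1 fall among 16 (adjusted p = 0.00626 with an estimated correlation), with Gbp2 at 4.61, and cell death genes 7 rises among 22 (adjusted p = 0.0118). Immediate early genes (7 and 1 of 25) and ribosomal protein genes (1 of 47 risen, 0 adjusted over the list alone, median 0.74) lost their list call. They had adjusted p = 0.346 and 0.451 with an estimated correlation. In all, 449 genes were higher and 435 lower. Of these calls 50.8% were higher, or 22.1% with limma and library totals. Library totals alone moved the median of all genes to −0.20. The 884 calls became 325 without replicate 2 of the TNF group, 293 and 429 without untreated polysome replicate 1 or 2, 1985 and 1992 without replicate 1 or 2 of the polysome dimerizer group, and 73 with the polysome libraries fitted alone.

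Between the stimuli in polysome RNA, Csf3 was higher with dimerizer by 7.19 ± 0.34, Cxcl1 by 4.58 ± 0.35, Nfkbiz by 4.15 ± 0.29, Ier3 by 3.80 ± 0.24 and Il6 by 3.74 ± 0.16. Ccl5 stood at −3.71 ± 0.37, Mmp9 at −2.61 ± 0.32 and the glucose transporter gene Slc2a6 at −2.13 ± 0.18. Ccl5 and Mmp9 missed the threshold with the polysome libraries fitted alone (adjusted p = 0.0618 and 0.0816). Malat1 (−2.59 ± 0.67) missed it there (−2.60, adjusted p = 0.194), without replicate 1 of the dimerizer group (−1.95, adjusted p = 0.0798) and without replicate 1 or 2 of the TNF group (−2.55 and −2.61, adjusted p = 0.1105 and 0.112). Higher with dimerizer were 16 of 25 immediate early genes (19 adjusted over the list alone), 11 of 14 MAP kinase feedback genes (13), 10 of 24 unfolded protein response genes (11) and 11 of 20 cholesterol genes (16). These lists had adjusted p = 0.0177, 0.00326, 0.0128 and 0.0149 with an estimated correlation. Cytokines had 11 higher and 4 lower of 23 (12 and 4 adjusted over the list alone, adjusted p = 0.00924 with an estimated correlation). Interferon-stimulated genes had 6 of 16 lower (10 adjusted over the list alone, adjusted p = 0.00924 with an estimated correlation). Matrix proteases (6 and 1 of 18), mitochondrial mRNAs (4 of 13 higher), cell cycle genes (1 lower) and ribosomal protein genes (0 called) lost their list call. In this order they had adjusted p = 0.119, 0.140, 0.440 and 0.755 with an estimated correlation. The median (−0.27) and mean (0.18) of NF-kB targets differed in sign. So did the cell death genes' median (−0.22) and upward test (camera adjusted p = 0.971), and neither list was called. In all, 623 genes were higher and 349 lower. Of these calls 64.1% were higher, or 44.9% with limma and library totals. Library totals alone moved the median of all genes to −0.21. The 972 calls became 1773 and 3178 without replicate 1 or 2 of the dimerizer group, 418 without replicate 2 of the TNF group, and 26 with the polysome libraries fitted alone.

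The ratio of polysome to total RNA asks whether ribosome loading changed beyond mRNA level. With dimerizer no gene passed in edgeR, 524 had an unadjusted p under 0.05, where chance gives 651.6, and DESeq2 called 2. The outcome depended on which replicate of the polysome dimerizer group was left out. These 2 replicates differed widely, and which of them deviates was not settled. Cxcl1 had a ratio change of 0.83 ± 0.44, Ccl2 of 0.46 ± 0.28 and Il6 of 0.03 ± 0.27. Ripk1 (−0.17 ± 0.40) and Ripk3 (−0.17 ± 0.27) also did not pass, and no list was called. With TNF no gene passed in edgeR, 657 had an unadjusted p under 0.05, where chance gives 651.6, and DESeq2 called 12. Il6 had a ratio change of −0.48 ± 0.27 and Ccl2 of 0.19 ± 0.28. With TNF ribosomal protein genes (median 0.73), MAP kinase feedback genes (−0.24) and mitochondrial mRNAs (−0.65) were called as lists with the preset correlation, with adjusted p = 0.899 for each with an estimated correlation. In simulated data 5 of 100 genes with a 2-fold change of this ratio were recovered and 61 of 100 with a 4-fold change. Most 2-fold changes were thus missed, and polysome pairs varied more than total RNA.

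In untreated cells, polysome RNA was poor in mitochondrial transcripts, translated inside mitochondria. Here mt-Nd1 (mitochondrial chromosome, 2751 to 3707) stood at 256.4 ± 24.2 CPM in polysomes against 7336 ± 620.8 in total RNA (−4.84 ± 0.31, adjusted p = 0.000297). Values were −5.34 ± 0.32 for mt-Co3 (4 against 285 counts) and −3.91 ± 0.36 for mt-Nd2. Of 13 mitochondrial mRNAs 9 were lower (12 adjusted over the list alone, adjusted p = 0.00354 with an estimated correlation). The share of reads on the mitochondrial chromosome was 0.118% to 0.435% in polysome libraries and 2.53% to 3.51% in total RNA. The linker histone gene Hist1h1b was higher in polysomes (3.51 ± 0.41), and of 15 replication-dependent histones 0 were called over all genes and 8 were higher adjusted over the list alone (adjusted p = 0.264 with an estimated correlation). Hist1h1b lost its call without polysome replicate 1 or 2 (3.48 and 3.54) or total RNA replicate 1 or 2 (3.14 and 4.07), mt-Tl1 (−3.45 ± 0.43) likewise (−4.48, −2.90, −3.40 and −3.50), and mt-Nd2 without polysome replicate 1 or 2 (−3.81 and −4.02). With a replicate block Hist1h1b (3.53, adjusted p = 0.124) and mt-Tl1 (−3.48, adjusted p = 0.158) lost it too. The 34 calls, 1 higher and 33 lower, became 3 and 5 without polysome replicate 1 or 2, 6 and 7 without total RNA replicate 1 or 2, and 261 (83 higher and 178 lower) without either polysome dimerizer library. The split was 444 higher and 266 lower without the expression filter, 143 and 180 with the gene length trend removed, 95 and 321 with DESeq2, and 68 and 325 with 1 model of all 24 libraries.

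Last, the 4 h dimerizer response was compared between the experiments, as the interaction of treatment and experiment. The response of Cyr61 (chromosome 3, 145646976 to 145649981) was higher by 3.21 ± 0.20 in total RNA of the snapshot. There it went from 212.8 ± 16.3 to 414.0 ± 23.5 CPM, while in the time course it went from 953.8 ± 2.42 to 201.0 ± 3.96 CPM. The early growth response genes Egr2 and Egr3 and the nuclear receptor gene Nr4a1 differed by 3.26 ± 0.31, 2.58 ± 0.29 and 2.20 ± 0.27, and Il6 by 1.75 ± 0.34. For Egr2 and Egr3 the treated levels were alike, 17.9 and 30.7 CPM in the snapshot and 18.2 and 30.5 CPM in the time course. Their untreated levels differed, 2.41 and 6.88 CPM against 23.7 and 41.1 CPM. For Nr4a1 both levels differed, 62.0 against 182.3 CPM untreated and 916.8 against 588.1 CPM treated. The small structural RNAs Rmrp (−6.15 ± 0.99) and Rpph1 (−6.80 ± 1.42), the growth factor gene Fgf2 (−2.00 ± 0.28) and the nuclear RNA Neat1 (−1.78 ± 0.25) had lower responses in the snapshot. Immediate early genes responded more in the snapshot, 8 of 25 (14 adjusted over the list alone, adjusted p = 0.00191 with an estimated correlation). So did 3 of 20 cholesterol genes (12 adjusted over the list alone) and 2 of 18 interferon-stimulated genes (5 adjusted over the list alone), with adjusted p = 0.00199 and 0.0132 with an estimated correlation. Ifit1 differed by 4.09 ± 0.83. Nrf2 targets responded less, with Hmox1 at −1.22 ± 0.18 and Nqo1 at −0.95 ± 0.19 (adjusted p = 0.000741 for the list with an estimated correlation).

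Of the other lists called for this difference, cytokines (2 of 24 higher), NF-kB targets (2 of 24), MAP kinase feedback genes (4 higher and 2 lower of 15), unfolded protein response genes (2 of 24), mitochondrial mRNAs (1 lower of 13), histones (0) and ribosomal protein genes (0) lost their call. They had adjusted p = 0.151, 0.286, 0.185, 0.185, 0.101, 0.438 and 0.765 with an estimated correlation. In all, 69 genes had a higher and 48 a lower response in the snapshot. Il6 lost its call without replicate 1 of the snapshot dimerizer group (1.69), time course untreated replicate 1 or 2 (1.76 and 1.74), snapshot untreated replicate 1 or 2 (1.65 and 1.87) or replicate 2 of the time course 4 h group (1.53). Rpph1 lost it without replicate 1 or 2 of the snapshot dimerizer group (−7.02 and −6.67), or time course untreated replicate 1 or 2 (−6.73 and −6.87). It also did without snapshot untreated replicate 1 (−6.04) or replicate 1 of the time course 4 h group (−5.92), and DESeq2 (−7.05) gave it no adjusted p. Neat1 lost its call with the gene length trend removed (−1.56, adjusted p = 0.209). The 117 calls became 50 and 62 without replicate 1 or 2 of the snapshot dimerizer group, and 33 and 44 without replicate 1 or 2 of its untreated group. They became 47 and 34 without time course untreated replicate 1 or 2, and 60 and 62 without replicate 1 or 2 of the time course 4 h group.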

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

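Of the tests here, that of library depth was chosen after the result was seen, and so were the controls with genes called at 3 h against 0.5 h and with genes of opposite signs. A difference between experiments and a signal outside the gene counts brought up the results below. The interaction of treatment and experiment at 4 h was called for 117 genes. The largest differences under the naming rule, in log2 from edgeR, were Egr2 (3.26), Cyr61 (3.21), Egr3 (2.58) and Nr4a1 (2.20), with Il6 at 1.75. Rpph1 (−6.80), Rmrp (−6.15), Fgf2 (−2.00) and Neat1 (−1.78) went the other way. Unmapped reads per 100 uniquely mapped ones averaged 8.96 ± 4.03 in the 4 h libraries of the time course, against 1.66 ± 0.36 in untreated cells.

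Why the 4 h response differed between experiments was weighed with 3 tests. The gene length trend is argued against as the whole cause, since 93.16% of the 117 genes stayed called after it was removed. Whether the response was further along in the snapshot cannot be told apart from a smaller response. Across 115 of these genes the difference correlated with the change from 2 h to 3 h at r = −0.7028, against a positive value predicted. But that change itself followed the change from 0.5 h to 3 h (r = 0.741), so the bound set was wrong, as a smaller response alone makes r negative. In the 20 genes where these changes had opposite signs, r was 0.178 (95% interval over genes −0.563 to 0.668), which decides nothing. Whether RNA left in nuclei contributes cannot be told apart from a generally smaller response in the snapshot: the median difference was −0.1778 over 2801 genes called higher at 4 h in the time course, but genes selected from other libraries, at 3 h against 0.5 h, had −0.11 over 2630 risen and 0.15 over 2682 fallen, so both directions were smaller. Differences in culture between the experiments stay open and untested, and the untreated levels of Cyr61, 953.8 CPM in the time course and 212.8 CPM in the snapshot, already differed.

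Nuclear RNAs were lower in untreated total RNA of the snapshot than in the time course, with Malat1 at −3.81, Meg3 at −2.70, Firre at −2.16 and Neat1 at −1.19 in log2. A candidate explanation is a lysate without nuclei in the snapshot. Over 5 further nuclear RNAs measured of 7 listed beforehand, the median difference was −0.757, with 4 below 0 (Mirg −1.31, Rian −1.15, Ftx −0.76, Tug1 −0.53, Pvt1 0.16), against 0.073 for all genes. The intronic share of reads, 2.05% to 2.65% against 5.54% to 8.91%, had been seen before this test and goes with it. A length trend is argued against, as the median was −0.6645 without it.

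In 2 pairs the libraries stood apart, at 1 h and in the polysome dimerizer group, and which one deviates was not tested. For the 1 h pair the SD over genes of 0.353 became 0.23 after removal of the length trend, against 0.173 at most in other pairs, so a length trend may be part of the cause but cannot be told apart from others, because the value lies between both bounds set. GC content (0.3369 after removal) and depth (a ratio of totals of 1.005) are argued against. For the polysome pair the SD of 0.557 became 0.4493 without the length trend and 0.5459 without the GC trend, against 0.299 and 0.349 at most in other pairs, which argues against either as the whole cause. No biological explanation was tested, since the design gives the partners the same treatment.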

How the results depend on the processing

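The fits with limma at a pseudocount of 0.5 (planned as the main test), with DESeq2, with the gene length trend removed, of total or polysome libraries alone, without libraries outside the groups compared, and with the authors' tables other than those of dimerizer in total RNA were chosen after the data were seen. Of 273 values of named genes, 200 were called, and 171 of these kept their call and direction under every alternative run for them. Another 29 lost it in some setting, and 19 uncalled values gained it, plus 3 of Mlkl below. Those not given in the report were Ripk3 at 1 h (−0.5004 without replicate 1 of that group), Ripk1 with TNF in polysomes (0.6994 with the length trend removed), and, for dimerizer against TNF in polysomes, Ccl2 (0.5295 with 1 model of all 24 libraries, 0.6984 without replicate 2 of the dimerizer group, 0.697 with the length trend removed) and Ripk3 (−0.7499 without that replicate). For polysome against total RNA they were Cxcl1 (−1.038 with the length trend removed) and Nfkbia (−0.6436 with 1 model, −0.6034 with DESeq2). Between experiments they were Ccl2 (0.9275, 0.9341 and 0.8831) and Cxcl1 (1.447, 1.439 and 1.403), each without the filter, with the length trend removed and with DESeq2. Among uncalled values, 116 changed sign in some setting. Counts of calls at 3 h and 4 h and between 4 h and 0.5 h stayed within 1.5 times under every alternative, and median-of-ratios scaling moved no count by more than that. Of 100 simulated 2-fold changes, 26 were recovered for dimerizer in total RNA and 66 at 4 h of the time course. The coefficient of variation was 0.203, pooled with polysome RNA, against 0.122. Unless stated otherwise, the cause of a shift was not tested.

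Besides some list medians and call majorities, the direction turned in 2 places. With limma and library totals, Mlkl was called lower (pseudocounts 0.1, 0.5 and 1) at 3 h (−0.36, −0.36 and −0.35), at 4 h (−0.37, −0.36 and −0.36) and between 0.5 and 4 h (−0.29 for each). These lie near this scaling's shift of the median of all genes. The correlation of the intergenic share with time (r = 0.528, permutation adjusted p = 0.070, rho = 0.057) became −0.6019 without the 4 h libraries, so it rests on those. The intronic share had r = 0.478 (permutation adjusted p = 0.12).

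Fewer list calls held with an estimated correlation, 91 instead of 161. Fitting the 6 total RNA libraries alone gave 7610 calls for dimerizer, 3910 for TNF and 6043 between them. The 6 polysome libraries alone gave 426, 73 and 26. Each fit pools the spread of 1 RNA type, wider in polysome RNA. Removing the length trend gave 938 calls at 1 h, 1656 and 1582 for dimerizer against TNF in total and polysome RNA, 323 for polysome against total RNA and 354 between experiments. DESeq2 gave 1148 and 1776 calls for TNF in total and polysome RNA, 2003 and 1916 for dimerizer against TNF, 2 and 12 for the ratios with dimerizer and TNF, 416 for polysome against total RNA and 413 between experiments. Without an expression filter the counts were 74 at 0.5 h, 849 at 1 h, 2 for the ratio with TNF, 710 for polysome against total RNA and 220 between experiments. With 1 model of all 24 libraries they were 1117 and 1856 for TNF, 2053 and 1984 for dimerizer against TNF, and 393 for polysome against total RNA. With limma at pseudocounts of 0.1, 0.5 and 1 they were 1405, 1500 and 1555 for TNF in polysomes and 1605, 1630 and 1654 for dimerizer against TNF in total RNA, and at 0.5 and 1 they were 182 and 239 between experiments.

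The authors' tables gave 76 calls at 1 h, 6454 at 2 h, 7218 and 5346 for dimerizer and TNF in total RNA, and 149 and 181 in polysome RNA. No gene called both there and here had opposite directions, and r of the log2 fold changes lay between 0.988 and 1.000 across genes. Their placeholders at 0 cover 23 of the 242 changes of at least 2-fold at 1 h and 289 of the 1942 between 0.5 and 4 h. The planned comparison with the authors' table for 4 h against untreated was not run, since the sheet of that name repeats total RNA of the snapshot.

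Leaving out single libraries gave 19 to 84 calls at 0.5 h, 242 to 3992 at 1 h and 1581 to 5620 at 2 h. The range was 1118 to 4227 for dimerizer in total RNA, 184 to 1129 for TNF in total RNA and 133 to 2256 between them. In polysome RNA it was 1422 to 4757 for dimerizer, 293 to 1992 for TNF and 418 to 3178 between them. It was 3 to 261 for polysome against total RNA and 33 to 62 between experiments, and the ratio with dimerizer reached 591 calls without replicate 2 of the polysome dimerizer group.

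Total and polysome samples share label numbers. As a check of pairing, the deviations of the same-numbered libraries from their group means had r = −0.287, 0.081 and −0.404 over genes, so the numbers were not taken as pairs. A fit with the number as a replicate block called 0 genes for either ratio (0 and 0) and 6 for polysome against total RNA instead of 34.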

Other observations

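The gene families below were chosen after the data were seen, and their p-values come from camera in limma with an estimated correlation, adjusted over 32 tests of 2 families. Hox genes, homeobox regulators of positional identity, were lower after dimerizer in both experiments. At 4 h of the time course 13 of 15 measured Hox genes fell (median −0.94, adjusted p = 0.0427), after 9 at 2 h (median −0.54, adjusted p = 0.0372) and 12 at 3 h (median −0.78, adjusted p = 0.0350). In total RNA of the snapshot 11 of 13 fell (median −1.34, adjusted p = 0.00581), and in polysome RNA 9 of 13 (median −1.30, adjusted p = 0.00581). TNF lowered 3 of 13 in total RNA (median −0.53, adjusted p = 0.00858) and 7 of 13 in polysome RNA (median −0.89, adjusted p = 0.00581). In the direct test in total RNA, 3 of 13 were lower with dimerizer than with TNF (median −0.66, adjusted p = 0.0247). In polysome RNA this list difference did not pass (median −0.45, adjusted p = 0.138). The ratio of polysome to total RNA of the family fell with TNF (median −0.38, adjusted p = 0.0427, 0 of 13 members called), and with dimerizer it did not pass (median −0.25, adjusted p = 0.447).

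Genes named Zfp, most of which encode zinc finger proteins, had 98 members lower and 29 higher of 265 at 4 h of the time course (median −0.35), and the family was not called (adjusted p = 0.436).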
